A study of Mus musculus with 4 samples.

How the data were processed

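Total RNA of the hypothalamus was extracted with Trizol and biotin-labelled for Affymetrix arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale, and MAS5 is the only tool named, without a version, per the submitters' processing notes. The scaling target, the annotation release and the genome build are not given in the sources used here, so no coordinates are printed. The authors' full sheet held 35474 probe sets and equalled the series' value table on every array (largest difference 0). Summed intensities were 68636594 to 68961786 per array, so the arrays had been brought to a common level before deposit. A second sheet of the authors kept the 25175 probe sets with a gene name. A further sheet kept 24914 of these, dropping 261. The sheet kept signals from 76.85 upward on the control A array and dropped those up to 76.84. The 16 ratio columns of the authors' sheets, each signal divided by the mean of the control arrays, were not used.

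From these intensities, log2 values were computed with no pseudocount and no further normalization. Detection calls were not used here, so the filter fixed for that case kept probe sets in the upper 60% of mean log2 signal, which corresponds to a signal of 717. As a measure of background, 1216 probe sets of olfactory and vomeronasal receptors had a median signal of 299 and a 95th percentile of 831, and 92.3% of them were removed by the filter. "Receptor range" means signals under that percentile. Where 1 group of a gene had its mean in that range, the fold given as "at least" took, on each array of that group, the higher of the signal and the percentile. This bound holds for the group means and does not allow for the spread between arrays. Of the named probe sets, 23015 had 1 gene identifier, covering 21265 genes, and 2160 had several and named no gene. Symbols were updated through the gene identifier with a RefSeq table of the assembly GRCm38.p6, which held 21637 of the 23015 probe sets. That changed 4460 symbols. Each gene was represented by the probe set with the highest mean log2 signal.

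Groups were compared with limma (lmFit and eBayes with an intensity trend), ΔFosB minus control, without a block and with Benjamini-Hochberg adjustment over 14520 genes at a threshold of 0.05. Standard errors are the moderated ones. Ranked genes, which are no significance call, have an unadjusted p under 0.01, a fold of at least 1.5 and groups that do not overlap. There were 211 of them, 79 higher and 132 lower. Of 31 gene lists, 29 had at least 4 tested members and were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were run beside it. The former rests on 2 residual degrees of freedom here, which leaves it little power. The preset treats the genes of a list as nearly independent, so its p-values may be too small where those genes move together. The pituitary list (3 tested) and the blood list (2 tested) were too short. Of these tested pituitary genes 0 passed in limma (1 at an unadjusted p under 0.05) and of the blood genes 0 passed (0 at an unadjusted p under 0.05). The pituitary gene Cga lay below the filter, with signals of 453 ± 30.3 in control and 1109 ± 293 in ΔFosB arrays. Fitted without a filter, it rose by 1.27 (SE 0.16, limma adjusted p = 0.00205), from a control signal in the receptor range. The other pituitary genes below the filter did not pass in that fit.

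The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took Fosb, Eno2, Gal, Agrp, Npy, Pomc and Cartpt always, then the 10 higher and 10 lower genes of largest log2 fold change among those past the threshold whose groups do not overlap. From each list it took up to 2 members with the highest and 2 with the lowest moderated statistic. Some genes that the rule takes are not reported here. The procedure was tested on simulated data for the same comparison of 14520 genes, with 200 changed genes. It recovered 76% of those changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold, with 15 false calls. The simulated noise was independent between genes and used limma's own variances, so shifts shared by many genes of an array were not tested.

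Alternatives were quantile normalization, median centring, pseudocounts of 16 and 64, no filter, the upper 40% of signal, the authors' low-signal filter, eBayes without a trend or with robust estimation, an unmoderated test, the mean of a gene's probe sets, each probe set as a feature, a replicate block, and leaving out each array in turn. A filter at the receptor 95th percentile was chosen after seeing the data. The series' value table was to be an alternative only if it differed, so it was not run. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.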

Results

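Hypothalamic RNA of male mice aged 12 weeks was profiled on 4 Affymetrix arrays. The hypothalamus is the brain region that governs feeding, body temperature, reproduction and pituitary hormone release. Of the arrays, 2 came from wild-type control mice and 2 from mice carrying ENO2-ΔFosB. ΔFosB is a shortened splice form of the transcription factor FosB, and Eno2 encodes neuron-specific enolase. Arrays are named by group and by the letters A and B of their titles. Each array held 35474 probe sets, with median signals of 917.52 (control A), 946 (control B), 976 (ΔFosB A) and 967 (ΔFosB B). The number of arrays limits the precision: the median standard error of a log2 fold change was 0.066. Nothing in the labels says that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical.

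The comparison of ΔFosB with control arrays asked how hypothalamic gene expression differed between the genotypes. On the ΔFosB arrays 13 of 29 tested neuropeptide genes rose and 1 fell, and 15 of 28 hypothalamic transcription factor genes rose and 3 fell. Camera's list adjusted p was 1.6e-10 and 6.46e-06 with the preset correlation, and 0.381 for each with an estimated one. Oxytocin was 8.13-fold higher and thyrotropin-releasing hormone 5.08-fold higher. In the group means the dopamine transporter gene Slc6a3 was at least 10.8-fold lower (9.39-fold without control replicate A). Its ΔFosB signal lay in the range of olfactory and vomeronasal receptor probe sets. All 20 tested genes of the myelin list fell (camera adjusted p = 7.22e-23 with the preset correlation, and 0.381 with an estimated one). The test with an estimated correlation rests on 2 residual degrees of freedom, which leaves it little power. The preset correlation of 0.01 treats the genes of a list as nearly independent. Yet thalamic genes, for example, differed together between arrays A and B of the same group, with median log2 differences of 0.41 in control and 0.63 in ΔFosB. The p-values with the preset correlation may therefore be far too small. Of 14520 genes tested, 1902 (13.1%) passed an adjusted p of 0.05 in limma's moderated test with n = 2 arrays per group. Of these, 898 were higher and 1004 lower on ΔFosB arrays. Most changes were small: 79 higher and 130 lower genes differed by at least 1.5-fold, and 14 and 25 by at least 2-fold. The signals of the groups did not overlap in 60.3% of the genes, against 33.3% by chance. The number called rests on limma's sharing of variance between genes, since an unmoderated test per gene called 0 genes (2690 at an unadjusted p under 0.05). It was 702 without control replicate A and 1255 without control replicate B.

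Fosb itself, the gene of the transgene product, had log2 signals of 10.34 in control and 10.86 in ΔFosB arrays, a log2 fold change of 0.52 (SE 0.13, limma adjusted p = 0.0389). Its signals were 1377 and 1220 on the control arrays and 1579 and 2189 on the ΔFosB arrays, which is higher on both. Where its probe set lies relative to the part carried by the transgene was not analysed here, so it may not check the genotype. The call ended without control replicate A (adjusted p = 0.0853), control replicate B (0.147) or ΔFosB replicate B (0.0684, log2 fold change 0.28). Eno2 had a log2 fold change of -0.05 (SE 0.04, adjusted p = 0.418). Of the 9 tested AP-1 factors, the family of dimers to which FosB belongs, 2 rose (Fosb and Fosl2), 0 fell and 7 did not pass, and 2 passed when adjusted over the list alone. Fosl2 rose by 0.35 (SE 0.08), a call that ended without control replicate A (adjusted p = 0.173) or ΔFosB replicate B (0.066). Fos had a log2 fold change of 0.06 (SE 0.17), which ran from -0.27 to 0.38 over the alternatives, and Jund of -0.05 (SE 0.05). The list as a whole did not pass camera's test (adjusted p = 0.0965).

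Among the genes with the largest increases was Fezf1, a transcription factor gene of the ventromedial hypothalamus. Its signal was 211.74 ± 38.1 in control and 2619 ± 243 in ΔFosB arrays (mean ± SD, n = 2), a log2 fold change of 3.64 (SE 0.12, adjusted p = 1.71e-06). Oxt, which encodes oxytocin, rose from 897 ± 62.9 to 7293 ± 539, a log2 fold change of 3.02 (SE 0.08, adjusted p = 5.77e-07). Trh rose by 2.34 (SE 0.09) and Avp, the vasopressin gene, by 2.24 (SE 0.17). The others of the 10 largest increases were Gal (1.72), Gda (1.48), Pdyn (1.46), Sytl4 (1.29), Dlx1 (1.249) and Ecel1 (1.15), each with both ΔFosB arrays above both control arrays. Gal encodes galanin, Pdyn prodynorphin and Gda guanine deaminase. The control signals of Fezf1, Pdyn and Sytl4 lay under 831, the 95th percentile of olfactory and vomeronasal receptor probe sets, so they were at least 3.15-fold, 1.83-fold and 1.92-fold higher, with that percentile as the level of the dim group. Where either group of a gene lay in this range, its log2 fold change is the measured difference of dim signals and "at least" marks this bound on the group means.

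Among the genes past the filter, Slc6a3 had the largest decrease, from 9022 ± 1724 in control to 744 ± 37.8 in ΔFosB arrays, a log2 fold change of -3.59 (SE 0.11, adjusted p = 1.38e-06). Aldh1a1, an aldehyde dehydrogenase gene, had a log2 fold change of -1.78 (SE 0.06). Slc10a4 (-1.75), Kcng4 (-1.69), Scn4b (-1.67), Slc18a2 (-1.54), Kcnab3 (-1.51), Nr4a2 (-1.503) and Th (-1.39) were also among the 10 largest decreases past the filter. Th encodes tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, and Slc18a2 the vesicular monoamine transporter. Kcng4, Scn4b and Kcnab3 encode subunits of potassium and sodium channels. On ΔFosB arrays the signals of Slc6a3, Kcng4 and Scn4b lay within the receptor range, so that they were at least 10.8-fold, 2.01-fold and 2.09-fold lower.

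**Figure D1:**
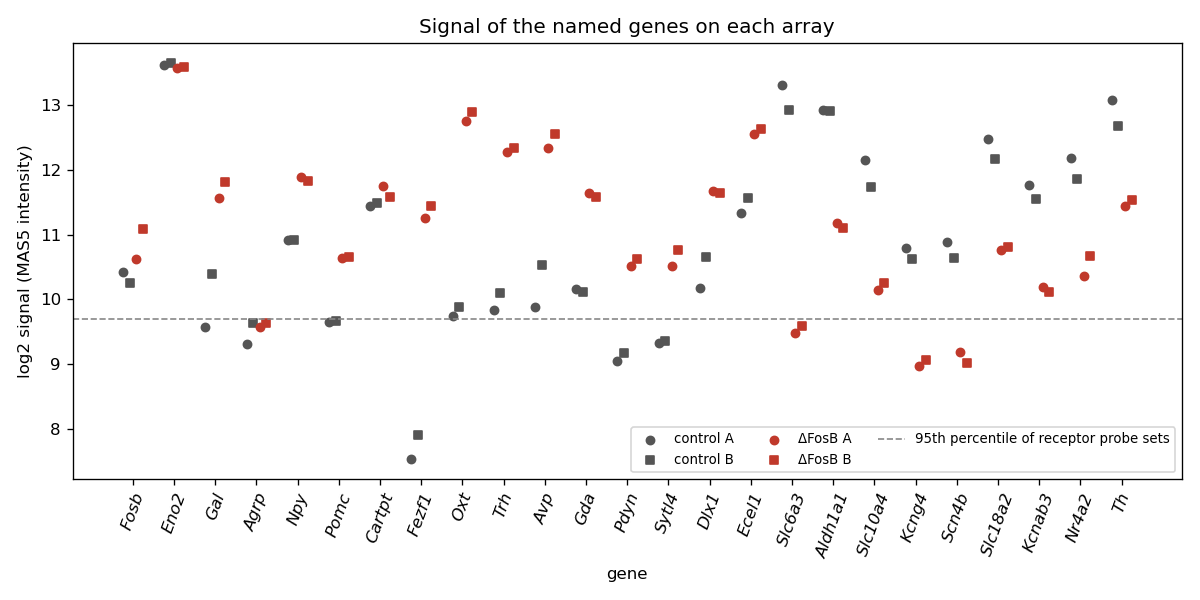
Log2 signal (MAS5 intensity, vertical axis) of Fosb, Eno2, appetite peptide genes and genes with large changes (horizontal axis) on the 4 arrays, with control in grey, ΔFosB in red, circles for arrays A and squares for arrays B. The dashed line is the 95th percentile of receptor probe sets, a signal of 831. Fezf1, Oxt, Trh and Avp lie higher on both ΔFosB arrays and Slc6a3 lies lower on both.

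Of 29 tested genes of the list of appetite and energy neuropeptides, 13 rose, 1 fell and 15 did not pass, and 20 passed when adjusted over the list alone. The orexigenic peptide gene Npy rose by 0.94 (SE 0.06, adjusted p = 8.12e-05) and Pomc, the precursor of melanocortins, by 0.98 (SE 0.06, adjusted p = 8.12e-05), at least 1.92-fold since its control signal lay in the receptor range. Gal rose by 1.72 (SE 0.21, adjusted p = 0.00159, but 0.123 with robust estimation). Cartpt had a log2 fold change of 0.21 (SE 0.07, adjusted p = 0.0863) and Agrp of 0.13 (SE 0.10, adjusted p = 0.438), the latter with both groups within the receptor range. Adcyap1, which encodes PACAP, fell by 0.57 (SE 0.07), and Cck had a log2 fold change of -0.87 (SE 0.33, adjusted p = 0.113), which was -1.43 without ΔFosB replicate A (adjusted p = 0.000487) and -0.31 without ΔFosB replicate B. The list was higher as a whole (camera adjusted p = 1.6e-10, and adjusted p = 0.381 with an estimated correlation). Myelin genes were lower on the same arrays, with a median log2 fold change of -0.55.

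Of 38 tested receptors for these peptides and for hormones, 17 rose, 3 fell and 18 did not pass, with 26 past the threshold adjusted over the list alone. Npy2r rose by 1.02 (SE 0.08) and the melanocortin receptor gene Mc3r by 0.92 (SE 0.07), at least 1.37-fold and 1.26-fold with control signals in the receptor range, while Adipor2 fell by 0.47 (SE 0.05) and Crhr1 by 0.41 (SE 0.06). Camera gave an adjusted p of 2.56e-05, and adjusted p = 0.381 with an estimated correlation. Of 28 hypothalamic transcription factors, 15 rose, 3 fell and 10 did not pass, with 21 adjusted over the list alone. Fezf1 and Dlx1 had the highest statistics, and Lhx1 fell by 0.36 (SE 0.07, and adjusted p = 0.0696 without control replicate A). The list was higher as a whole (adjusted p = 6.46e-06, and adjusted p = 0.381 with an estimated correlation).

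Of 17 tested genes of monoamine and cholinergic signalling, 0 rose, 7 fell and 10 did not pass, with 10 adjusted over the list alone. Slc6a3 and Slc18a2 had the lowest statistics. The members with the highest, Drd1 and Adra2a, had log2 fold changes of 0.24 (SE 0.08, adjusted p = 0.0708) and 0.23 (SE 0.10, adjusted p = 0.153). The list was lower (camera adjusted p = 0.000192, and adjusted p = 0.381 with an estimated correlation). With no filter 2 of 22 rose and 7 fell. Those that rose were the cholinergic genes Chat (0.44, SE 0.11, limma adjusted p = 0.0415) and Slc5a7 (0.50, SE 0.11, adjusted p = 0.0303), both groups lying in the receptor range. The cholinergic gene Ache had a log2 fold change of 0.05 (SE 0.05), so the fall of the list is not one of its cholinergic genes. Of 22 genes of GABA signalling, 8 rose, 2 fell and 12 did not pass, with 13 adjusted over the list alone. The receptor subunit genes Gabrq and Gabre rose by 0.82 (SE 0.07) and 1.12 (SE 0.11), and Gabbr2 fell by 0.19 (SE 0.04) (list adjusted p = 0.0465, and adjusted p = 0.381 with an estimated correlation). The Gabbr2 call ended without an intensity trend (adjusted p = 0.0689) and without control replicate A (0.161), control replicate B (0.0754) or ΔFosB replicate B (0.0975). Of 26 genes of glutamate signalling, 5 rose and 5 fell, with 11 adjusted over the list alone. Grik3 rose by 0.50 (SE 0.07) and Grm2 fell by 0.79 (SE 0.07). That list did not pass (adjusted p = 0.573), and its median log2 fold change was 0.06 while its mean was -0.05.

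The genes of oligodendrocytes and myelin all fell, 20 of 20 tested, and 20 adjusted over the list alone. Mog fell by 0.83 (SE 0.05) and Mag by 0.72 (SE 0.05), while the smallest statistics belonged to Olig1, which fell by 0.29 (SE 0.06), and Olig2, which fell by 0.34 (SE 0.07). Olig1 did not pass without control replicate A (adjusted p = 0.0741), control replicate B (0.0658) or ΔFosB replicate B (0.0689), nor Olig2 without control replicate B (0.0736). Camera gave an adjusted p of 7.22e-23, and adjusted p = 0.381 with an estimated correlation. Of 8 genes of oligodendrocyte precursors, 1 rose and 3 fell (adjusted p = 0.189), with 4 adjusted over the list alone. C1ql1 fell by 0.76 (SE 0.08) and Bmp4 had a log2 fold change of 0.31 (SE 0.08, adjusted p = 0.0449), at least 1.13-fold with a control signal in the receptor range. The Bmp4 call ended with quantile normalization (0.24, adjusted p = 0.121), with no filter (0.0668) or the authors' low-signal filter (0.0501), and without control replicate A (0.151), control replicate B (0.128) or ΔFosB replicate B (0.20, adjusted p = 0.201).

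Of 13 genes of ependymal cells and tanycytes, which line the third ventricle, 6 rose and 1 fell, with 9 adjusted over the list alone. Gpr50 rose by 1.04 (SE 0.07) and Scn7a by 0.89 (SE 0.09), and Dio2 fell by 0.62 (SE 0.11) (list adjusted p = 0.000154, and adjusted p = 0.381 with an estimated correlation). Dio2 did not pass without control replicate A (adjusted p = 0.0549). Of 16 astrocyte genes, 1 rose and 4 fell, with 9 adjusted over the list alone: Aqp4 fell by 0.54 (SE 0.06) and Slc1a3 rose by 0.37 (SE 0.05) (list adjusted p = 0.0131, and adjusted p = 0.479 with an estimated correlation). Of 15 vessel genes, 0 rose and 6 fell, with 6 adjusted over the list alone, including Rgs5, which fell by 0.42 (SE 0.06) (list adjusted p = 0.0207, and adjusted p = 0.465 with an estimated correlation). Of 20 general neuronal genes, 1 rose and 4 fell, with 6 adjusted over the list alone. The neurofilament genes Nefm and Nefh fell by 0.63 (SE 0.05) and 0.65 (SE 0.06), and Syn2 rose by 0.27 (SE 0.05, and adjusted p = 0.0859 without control replicate A) (list adjusted p = 0.0221, and adjusted p = 0.482 with an estimated correlation).

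Of 7 meningeal and fibroblast genes, 2 rose and 0 fell, and of 8 choroid plexus genes, 3 rose and 0 fell, with 3 and 5 adjusted over each list alone (both lists adjusted p = 0.0221). These calls had adjusted p = 0.563 and adjusted p = 0.535 with an estimated correlation. The meningeal genes past the threshold were Col1a1 (0.22, SE 0.06, adjusted p = 0.0482) and Col1a2 (0.33, SE 0.08, adjusted p = 0.0363). Both calls ended with quantile normalization (adjusted p = 0.0657 and 0.0638), no filter (0.0669 and 0.0516), and without control replicate A (0.249 and 0.219) or ΔFosB replicate B (0.124 and 0.117). That of Col1a1 also ended with the authors' low-signal filter (0.0591) and without control replicate B (0.107) or ΔFosB replicate A (0.0776). Of 10 genes of cortex and hippocampus, 5 rose and 1 fell, with 9 adjusted over the list alone. Nptx1 rose by 0.65 (SE 0.06), and the list had adjusted p = 0.0202, and adjusted p = 0.381 with an estimated correlation. Slc17a7, with a ΔFosB signal in the receptor range, was at least 1.62-fold lower in the group means but did not pass (adjusted p = 0.142). This bound was 1.01-fold without control replicate A (adjusted p = 0.563) and 2.59-fold without control replicate B (0.0643). Without ΔFosB replicate A it was 1.95-fold and the gene passed (0.00134), and without ΔFosB replicate B the log2 fold change was -0.42 (0.484). In the respiratory chain list, 4 of 43 genes fell and 0 rose, with 4 adjusted over the list alone, and the median log2 fold change was -0.12 (adjusted p = 1.45e-08, and adjusted p = 0.381 with an estimated correlation). Among 34 ribosomal protein genes, 0 passed in limma (8 at an unadjusted p under 0.05), with 0 adjusted over the list alone, and the median was 0.06 (adjusted p = 0.0465, and adjusted p = 0.568 with an estimated correlation).

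Lists tied to ΔFosB and bone were also fixed. Of 10 reported brain targets of ΔFosB, 2 rose and 0 fell, with 3 adjusted over the list alone. Pdyn rose by 1.46 (SE 0.08) and Calb1 by 0.30 (SE 0.05). Cdk5 had a log2 fold change of -0.10 (SE 0.07) (list adjusted p = 0.0465, and adjusted p = 0.381 with an estimated correlation). Of 13 neural regulators of bone mass, 5 rose and 2 fell, with 11 adjusted over the list alone. Npy2r rose by 1.02 (SE 0.08), again at least 1.37-fold, and Mc4r by 0.69 (SE 0.08), and Chrm3 and Htr2c fell by 0.41 (SE 0.07) and 0.30 (SE 0.06) (list adjusted p = 0.0465, and adjusted p = 0.381 with an estimated correlation). Htr2c did not pass without control replicate A (adjusted p = 0.0696).

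The remaining lists did not pass. Of 20 immediate early genes, 3 rose and 3 fell (adjusted p = 0.243), with 8 adjusted over the list alone. Nptx2 rose by 0.57 (SE 0.08), and Nr4a2, also a gene of dopamine neurons, fell by 1.503 (SE 0.12). Of 27 genes of leptin, insulin and energy-sensing signalling, 3 rose and 3 fell (adjusted p = 0.868), with 8 adjusted over the list alone. Stat5b rose by 0.34 (SE 0.06) and Ppargc1a fell by 0.39 (SE 0.05). The median and mean of that list lay above 0 and camera's direction was down. Among 16 circadian clock genes, 0 passed in limma, and 0 adjusted over the list alone (3 at an unadjusted p under 0.05; list adjusted p = 0.571). The striatal list had 2 genes higher and 5 lower of 11, with 8 adjusted over the list alone (adjusted p = 0.571). The thalamic list had 1 higher and 0 lower of 12, with 3 adjusted over the list alone and a median of -0.46 (adjusted p = 0.156). Microglia and macrophages had 0 higher and 1 lower of 16 (adjusted p = 0.166), with 0 adjusted over the list alone. Heat shock genes had 1 higher and 0 lower of 16 (adjusted p = 0.208), with 1 adjusted over the list alone. Interferon genes had 0 higher and 1 lower of 9 (adjusted p = 0.166), with 1 adjusted over the list alone, namely Ifit2, which fell by 0.69 (SE 0.07), at least 1.12-fold with a ΔFosB signal in the receptor range. Of the 4 tested sex-linked genes 0 passed in limma (0 at an unadjusted p under 0.05; list adjusted p = 0.945), with 0 adjusted over the list alone.

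**Figure D2:**
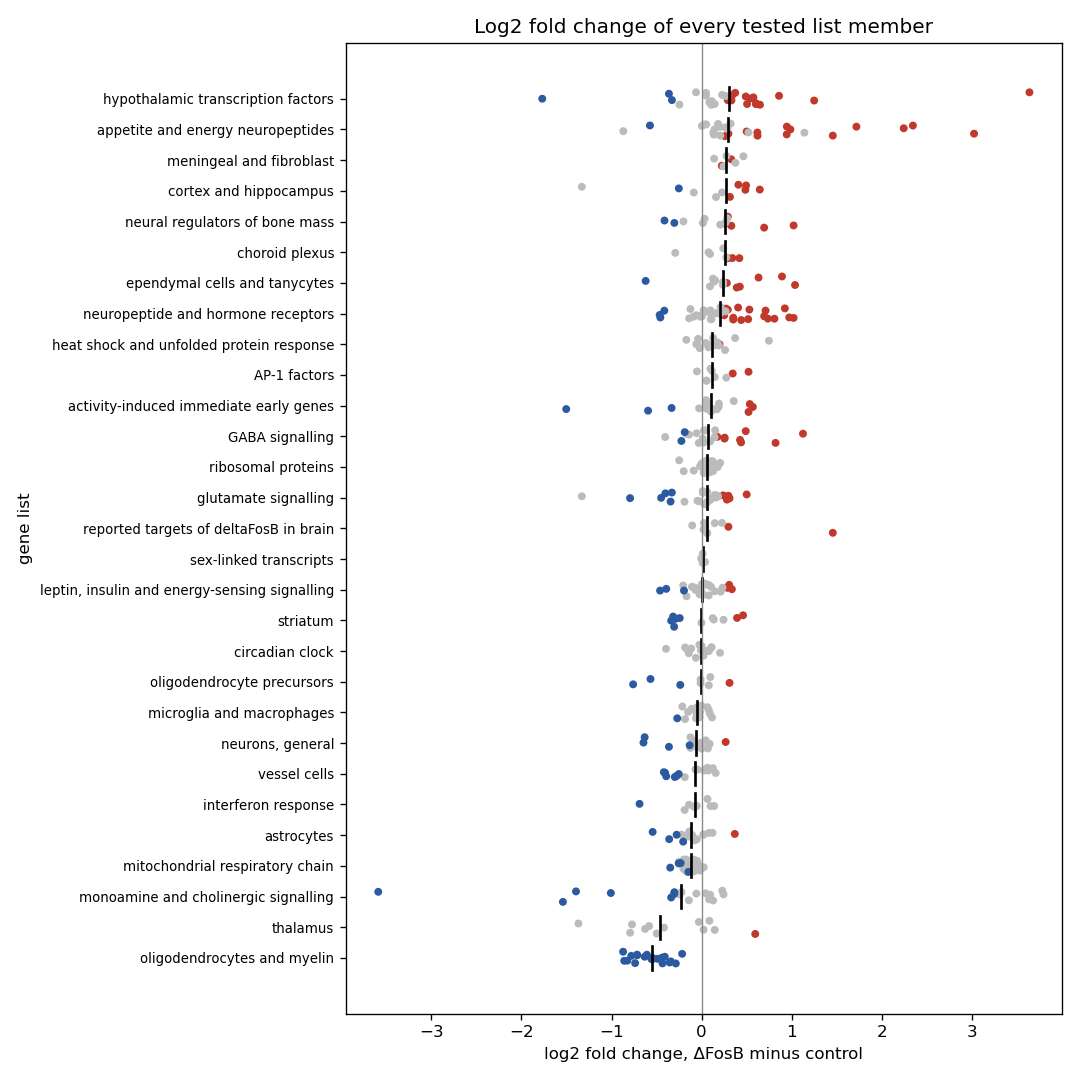
Log2 fold change (ΔFosB minus control, horizontal axis) of every tested member of the 29 lists (vertical axis), with genes past an adjusted p of 0.05 in red where higher and in blue where lower, the others in grey, and the list median as a black bar. The median of the oligodendrocyte and myelin list lies at -0.55 and that of the hypothalamic transcription factors at 0.31.

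In all, 17 of the 29 lists passed camera's test, 11 higher and 6 lower on ΔFosB arrays. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05), and fry's rotation test called 10, all among the 17. Lists called numbered 11 without ΔFosB replicate B, where the calls of ΔFosB targets (adjusted p = 0.134), bone mass (0.0645), general neurons (0.0953), meninges (0.712), choroid plexus (0.175) and ribosomal proteins (0.369) ended. Those of general neurons (0.0882) and choroid plexus (0.0969) also ended without control replicate A, that of ribosomal proteins without control replicate B (0.267) and that of vessels without ΔFosB replicate A (0.126). Quantile normalization ended the calls of general neurons (0.0776) and choroid plexus (0.055), median centring that of bone mass (0.0541), and no filter those of ΔFosB targets (0.0789), GABA signalling (0.102), choroid plexus (0.13) and ribosomal proteins (0.164). The authors' low-signal filter ended those of ΔFosB targets (0.072), GABA signalling (0.101), choroid plexus (0.115) and ribosomal proteins (0.16). The upper 40% of signal ended those of ΔFosB targets (mean log2 fold change 0.22 to 0.08, adjusted p = 0.1), bone mass (0.19 to 0.09, adjusted p = 0.246) and general neurons (0.0823). The filter at the receptor 95th percentile ended those of bone mass (mean 0.11, adjusted p = 0.218) and choroid plexus (0.18 to 0.09, adjusted p = 0.244).

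Counts of genes past the threshold also moved with single arrays, and for immediate early genes down as well as up. Those of the GABA, glutamate and leptin lists moved too. With each array left out in turn, 12 to 17 neuropeptide genes, 11 to 15 hypothalamic transcription factors and 12 to 15 receptors rose, while 17 to 20 myelin genes and 5 to 9 monoamine and cholinergic genes fell. Without control replicate A, 0 AP-1, 0 meningeal and 0 choroid plexus genes rose, 2 genes of the bone list rose, and 0 respiratory chain, 0 striatal and 3 vessel genes fell. Without control replicate B, 1 AP-1 and 1 meningeal gene rose, and 1 vessel, 2 striatal and 2 thalamic genes fell. Without ΔFosB replicate A, 4 AP-1, 8 immediate early, 5 meningeal and 5 heat shock genes rose, and 7 thalamic genes and 2 astrocyte genes fell. Without ΔFosB replicate B, 0 AP-1, 0 meningeal and 1 choroid plexus gene rose, and 1 AP-1, 1 respiratory chain and 2 striatal genes fell.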

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

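The tests of scaling and of other splits, the region lists and their restriction to members above the receptor range were chosen only after the main results were seen. Bootstrap intervals, here and in the later sections, resample the genes of a list. They do not measure the spread between arrays, and genes of a list are not independent replicates.

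Probe sets that the main comparison left out carried differences too. Those with several gene identifiers entered only the alternative with each probe set as a feature. In a fit of all probe sets above the filter, 45 of 4140 probe sets without a gene name were higher and 65 lower on ΔFosB arrays. Fitted alone, the same set gave 0 calls in limma (597 at an unadjusted p under 0.05). Of 1376 probe sets with several gene identifiers, 16 were higher and 22 lower in the fit of all probe sets, against 5 and 5 when fitted alone.

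The pattern weighed first is the fall of dopamine-neuron genes with the rise of hypothalamic peptide genes. An array-wide scaling difference was weighed with 29 neuropeptide genes and 17 tested dopamine-neuron genes, the latter list written after its largest falls were seen. A single factor per array cancels in a difference between lists, so that difference cannot test such a factor. Quantile normalization also removes a shift that changes with signal. After it the median log2 fold change of the neuropeptide genes still lay 0.72 (95% bootstrap interval 0.47 to 1.84) above that of the dopamine-neuron genes. The genes called went from 1902 to 1645, 1539 of them shared. For more midbrain tissue on control arrays, a list of 18 genes of midbrain nuclei other than dopamine neurons was to fall, but its median was 0.044 (95% bootstrap interval -0.015 to 0.132), which met the bound written against this explanation. Because 10 members lay in the receptor range, where a gene excludes nothing, the bound was then applied, with that first result known, to the 8 brighter members, whose median of 0.023 (-0.064 to 0.169) leaves the explanation undecided. Less posterior hypothalamus is undecided as well (median -0.0745, -0.363 to 0.0507, 8 members). Its list shares Lmx1a, Lmx1b and Foxa1 with the dopamine-neuron list, so it cannot separate posterior hypothalamus from dopamine neurons. Of its 11 genes, 4 were already in fixed lists. The genotype, untested as a cause, may also account for the pattern.

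The second pattern is the fall of myelin genes. That 100% of the 20 members fell restates the pattern, so a lower share of mature oligodendrocytes or white matter was not decided. It stays open beside the genotype, and neither was tested separately. The third pattern lies between arrays of different letter. Thalamic genes were higher on the A array in both groups, with medians of 0.41 in control (0.27 to 0.64) and 0.63 in ΔFosB (0.23 to 0.84). These values restate the pattern, so more thalamus on the A arrays was not decided, and no biological explanation was tested.

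Of the 3 ways to split the 4 arrays evenly, 1 (the real one) gave as many genes as the 1902 called, and the highest other count was 0 (175 and 36 genes at an unadjusted p under 0.05 in limma). The splits are too few for a share under 0.05. In each other split the difference between control and ΔFosB arrays enters the residual spread, so few calls were bound to result there. The comparison of counts therefore cannot decide whether the 1902 calls arose by chance.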

How the results depend on the processing

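The alternatives were fixed before the data were examined, except the filter at the receptor 95th percentile. Signals near the receptor range limit what can be read from dim genes, and with 2 arrays per group every call leans on variance shared between genes. The Fosb call was lost with quantile normalization (0.51, adjusted p = 0.0616), no filter (0.52, adjusted p = 0.0511), robust estimation (0.52, adjusted p = 0.123) and the unmoderated test (0.52, adjusted p = 0.409), with no change of direction. Leaving out each array in turn gave Fosb values of 0.28 to 0.76, and over 17 alternatives it passed in 10, with adjusted p from 2.74e-05 to 0.409. The cause was not tested. The unmoderated test called 0 genes, 0 higher and 0 lower (2690 at an unadjusted p under 0.05), and ranked 91. The upper 40% of signal gave 520 higher genes, from fewer genes tested (9844), and left the meningeal (3 tested) and choroid plexus (0 tested) lists too short to test. Without an array, with the lone array of its group assumed to vary like the other group, the count ranged from 702 to 1697, with 253 to 749 higher and 449 to 948 lower. Without control replicate A it was 702, of which 36.0% were higher against 47.2% in full. Without control replicate B it was 1255, and without ΔFosB replicate B 598 were higher. List calls ranged from 11 to 20, with 11 without ΔFosB replicate B. Camera with an estimated correlation called 0 lists (2 at an unadjusted p under 0.05) and fry 10. Of the named genes, Fos reversed, to -0.27 (adjusted p = 0.0495) without ΔFosB replicate B, with a range of -0.27 to 0.38 and adjusted p from 0.00745 to 0.931 over its alternatives.

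The labels do not say what the letters A and B stand for, so a batch or dissection shared by a letter was not tested. The A minus B differences of the control and of the ΔFosB arrays correlated at 0.24 across genes, which are not independent replicates. With a replicate block 3824 genes passed, 1936 higher and 1888 lower, including all 1902. In that fit 1 of 12 thalamic genes was higher and 7 were lower. The block leaves fewer than the main fit's 2 residual degrees of freedom, so these calls lean still more on variance shared between genes.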

Other observations

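The gene lists in this part were written after the largest changes had been seen, so their direction is no independent evidence. Genes of midbrain dopamine neurons fell broadly: without a filter 16 of 23 fell and 0 rose, with a median log2 fold change of -0.56 (95% bootstrap interval -1.39 to -0.30). Besides Slc6a3 and Th, these included the nicotinic receptor gene Chrna6, chosen after its values were seen, which fell by 3.64 (SE 0.15) and had a mean signal below the filter. Its ΔFosB signal lay in the receptor range, so it was at least 2.96-fold lower. The receptor tyrosine kinase gene Ret, chosen likewise, fell by 1.21 (SE 0.09). The developmental regulators Foxa1, Lmx1b and Pitx3, also chosen after their values were seen, had log2 fold changes of 0.05, 0.11 and 0.14. Of the 23 genes, 9 were in a fixed list and 15 stayed above the receptor range on ΔFosB arrays.

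Genes of the anterior and medial hypothalamus rose in 15 of 21 cases without a filter, and 0 fell, with a median of 0.41 (0.33 to 0.57). Of these 21 genes, 18 were already in fixed lists. In the list of mammillary and posterior hypothalamus 2 of 11 fell and 0 rose, with a median of -0.06 (-0.16 to 0.11). Lhx1 was among those that fell. Among the fast-conducting projection neuron genes 7 of 14 fell and 1 rose without a filter, including Kcna2, which fell by 0.50 (SE 0.06), and Cplx1, which fell by 0.51 (SE 0.07), both picked as examples from the finished list after their values were seen. In the list of midbrain nuclei other than dopamine neurons 1 of 18 fell and 0 rose.

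The test of midbrain nuclei, at first against extra midbrain tissue on control arrays, left it undecided on the brighter members (median 0.023). After the first of these results a further hypothesis was tried: that control arrays hold more fast-conducting projection neurons of regions outside the hypothalamus. The list of 14 genes left out genes already seen to fall and was written before its members' values were seen, although genes of the same kind had been seen to fall. The median of its 13 members above the receptor range was -0.35 (95% bootstrap interval -0.50 to -0.30), which is what this hypothesis needs. A change within such neurons would give the same value, so the test may not separate tissue from genotype. Of the 14 genes 0 were in a fixed list, and 12 stayed above the receptor range on ΔFosB arrays.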
